A study of Homo sapiens with 12 samples.

How the data were processed

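RNA was sequenced from SW480, a cell line from a human colorectal adenocarcinoma, in 12 libraries. Per the labels, 3 were untreated, 3 were treated with PUE, 3 with GLY and 3 with both (GLY_PUE). The abbreviations are kept as given. Per the labels' protocols, cells were grown for 12 h in medium with 10% serum and then for a further 12 h with or without treatment, and libraries were made from 0.5 µg of RNA for the BGISEQ-500 platform. The GLY libraries carry 12, 13 and 14 h in their labels, while the protocol gives 12 h, and both are reported as stated. The protocol also names BER and WOG, which were not analysed here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

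The authors deposited a single table of 3699 genes. Per the file headers it holds a read count per gene and library. These are estimated counts deposited without normalization, of which 58.2% were whole numbers. It also holds an expression value per gene and library, which the authors' headers leave without a unit and which behaves as FPKM. Per the file headers, the remaining columns are the authors' log2 ratios between groups and the authors' p-values and q-values. TopHat and DESeq 1.32.0 are named in the submitters' processing notes with no role. The counting tool, genome build and annotation are not given in the sources used here, and no coordinates were used. Every gene in the table had an absolute log2 ratio of at least 1 and a q-value of at most 0.001 in at least 1 of the authors' comparisons, as tested on the values. The table is therefore a selected list: counts of calls within it are not independent evidence of a response, gene list tests compare members only with other selected genes, and a gene absent from it was not analysed here. Of the 3699 genes, 3647 were marked as mRNA, 30 as long non-coding RNA and 20 as pseudogenes.

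Because the table holds part of each library, its column sums are not library depths. Relative library totals were recovered from the ratio of count to FPKM over 625 genes with at least 100 counts and an FPKM of at least 5 in every library. They were placed on an absolute scale with the lengths of 83 genes that have a single transcript in GENCODE release 29, which gave 20.1 M reads for the first untreated library (95% interval of the slope, 19.6 to 20.3). Totals ranged from 19.6 to 21.3 M reads. The listed genes held 14.3% ± 0.526 of reads in untreated, 14.3% ± 0.511 in PUE, 14.8% ± 0.748 in GLY and 15.2% ± 0.11 in GLY_PUE libraries (SD, n = 3). With these depths a count of 0 allows up to 0.153 CPM (counts scaled to a library of 1e+06 reads), counting error only.

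Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, a robust quasi-likelihood fit of the 4 groups over all 12 libraries, and Benjamini-Hochberg adjustment over the 3429 genes left, with an adjusted p under 0.05 as the threshold. The design, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. That design scaled libraries by TMM. TMM assumes that most genes tested do not change, which need not hold in a list selected for change, so after the data had been examined the recovered library totals were taken as the main scaling, and TMM within the table was kept as the alternative. The choice matters. TMM raises log2 fold changes by 1.13 for GLY and 1.01 for GLY_PUE against untreated, so values below are changes relative to library totals and the TMM split is given beside them.

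The named genes are, per comparison with untreated, the 10 largest increases and 10 largest decreases among called genes with an average log2 CPM of at least 1 and groups that do not overlap, up to 4 members with the smallest p of each list described, and 7 Wnt genes. Between treatments they are the 5 largest in each direction, or, with fewer than 5 called genes, the 5 with the smallest p. Every gene this rule gives, over all lists tested, was carried through every alternative, and the text gives examples picked from them with their values in view. Genes outside the rule are marked as chosen after their values were seen. A count of list members below covers only members in the table. Examples are 29 of 38 Wnt targets, 13 of 40 core Wnt components and 12 of 22 unfolded protein response genes. Of NRF2, p53, ATF4 and apoptosis genes the table held 9 of 25, 11 of 26, 14 of 30 and 5 of 26. Of 38 gene lists, 28 had at least 3 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry as alternatives, and adjusted over the lists of each comparison. Other alternatives were TMM and RLE scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, only the libraries compared, a replicate block, stricter thresholds and each library left out. Leaving out the libraries numbered 3, a term for them, and fits on the compared groups with the block or without number 3 were added after the data had been examined.

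Replicate numbers are shared between groups. Deviations from the group means of same-numbered libraries correlated across 1938 genes at 0.693 or more between untreated and PUE, 0.317 or more between untreated and GLY_PUE, 0.307 or more between PUE and GLY_PUE, 0.113 or more between GLY and GLY_PUE and 0.109 or more between PUE and GLY. The lowest between untreated and GLY was 0.0605. By the criterion of 0.1 in every pair the numbers therefore pair the libraries in all comparisons but GLY against untreated and the interaction. This pairing comes from the data, not from the labels. No pair of libraries differed by less than sampling noise, and none were merged. The closest were PUE replicates 1 and 2, with a chi-square per gene of 2.14, and untreated and PUE replicate 1 (2.18), where sampling noise gives 1. Untreated and PUE replicate 2 differed by 3.09, and untreated replicates 1 and 2 by 2.67. A shared number thus did not always mark the closer libraries.

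The procedure was tested on simulated counts with 200 changed genes, 50 per fold size. They were drawn without shifts by replicate number and with the spread of the fit of all 12 libraries. For PUE against untreated, with 3365 genes tested, it recovered 4% of genes changed by 1.5-fold, 18% at 2-fold, 56% at 3-fold and 80% at 4-fold. For GLY_PUE against GLY, with 3381 genes tested, it recovered 0%, 10%, 58% and 78%. Genes that share reads with close copies (KRT16, HSPA1A and HSPA1B, the metallothioneins, UGT1A6, histone genes, SPRR2D) and read-through symbols are uncertain, since the counting of shared reads is not stated.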

Results

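The libraries separated by GLY. The first principal component of log2 CPM, with 81.4% of the variance, set the 6 libraries treated with GLY or GLY_PUE apart from the 6 untreated and PUE libraries. The authors' columns mark 2878 of the 3699 listed genes in GLY against untreated. The selection thus favours this separation, and the share of variance does not describe all expressed genes. GLY replicate 1 stood apart on the second component (10.8%), and the libraries numbered 3 stood apart from numbers 1 and 2 in every group. Untreated replicates 1 and 3 differed with a chi-square per gene of 76.4, untreated and PUE replicate 3 with 3.11.

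**Figure D1:**
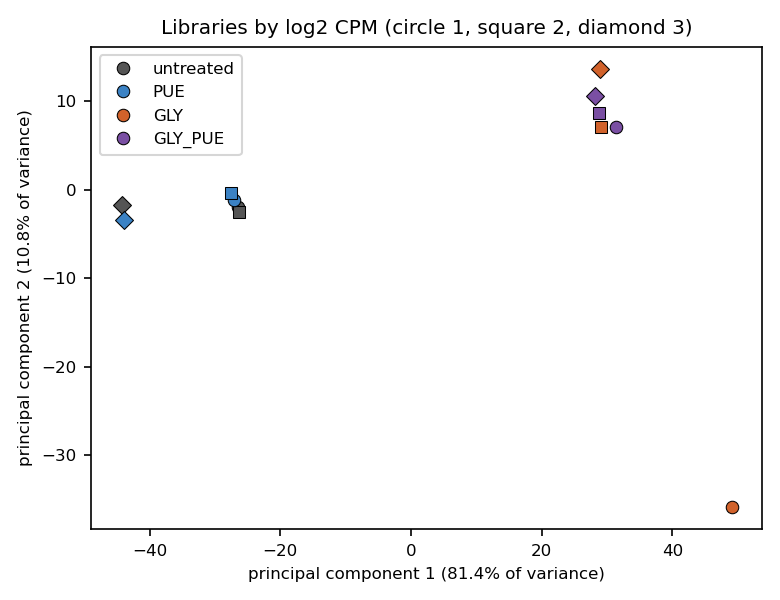
Position of the 12 libraries on the first principal components of log2 CPM, by group (colour) and replicate number (shape). The horizontal axis holds 81.4% of the variance and the vertical axis 10.8%, among genes that the authors selected for change. GLY replicate 1 lies at the lower right, away from the other libraries treated with GLY.

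After GLY, targets of Wnt signalling fell against untreated cells. AXIN2, a negative regulator of the pathway that is also one of its targets, went from 546 ± 18.8 to 106 ± 17.8 CPM (SD, n = 3 each; log2 fold change −2.37, SE 0.21, adjusted p = 1.57e-05). APCDD1 (−4.64, SE 0.37), the transcription factor SP5 (−3.74, SE 0.32), the ubiquitin ligase RNF43 (−3.03, SE 0.26), the secreted inhibitor DKK4 (−5.46, SE 0.85) and the receptor LGR5 (−5.20, SE 1.08) were lower too. Without untreated replicate 3, DKK4 was at −4.32 and LGR5 at −4.15. MYC moved the other way, from 408 ± 88.1 to 1079 ± 325 CPM (1.40, SE 0.26, adjusted p = 0.000715). Of 29 tested Wnt targets, 26 fell and 3 rose, the 3 being MYC, DKK1 (1.47) and VEGFA (0.84), which were named after their values were seen. As a list they were lower than the other listed genes (camera, adjusted p = 0.00113), but adjusted p = 0.349 with an estimated correlation, and over the camera alternatives the values ran from 0.000519 to 0.349. Under TMM, 18 fell and 3 rose.

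Among pathway components, CTNNB1, which encodes beta-catenin, fell from 716 ± 85.2 to 256 ± 134 CPM (−1.48, SE 0.35, adjusted p = 0.00275). The cyclin gene CCND1, named by the rule and not as a component, fell by 1.60 on the log2 scale (SE 0.27). Neither the CTNNB1 nor the CCND1 call held under TMM (−0.40 and −0.46). CTNNB1 stood at 106 CPM in GLY replicate 1 against 365 and 297 in the others. APC did not pass (−1.05, SE 0.57, adjusted p = 0.0951). Without GLY replicate 1 it was −0.54 with an adjusted p of 0.0341, where values over all alternatives ran from 0.0321 to 0.987. GSK3B is absent from the table and was not analysed here. Of 13 core components 10 fell, among them WLS (−2.02), FZD1 (−2.13), FZD2 (−1.93) and TLE3 (−1.15), and 1 rose, but the list did not differ from the other listed genes (adjusted p = 0.259). Under TMM 2 fell and 1 rose, and TLE3 had the other sign (0.02).

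**Figure D2:**
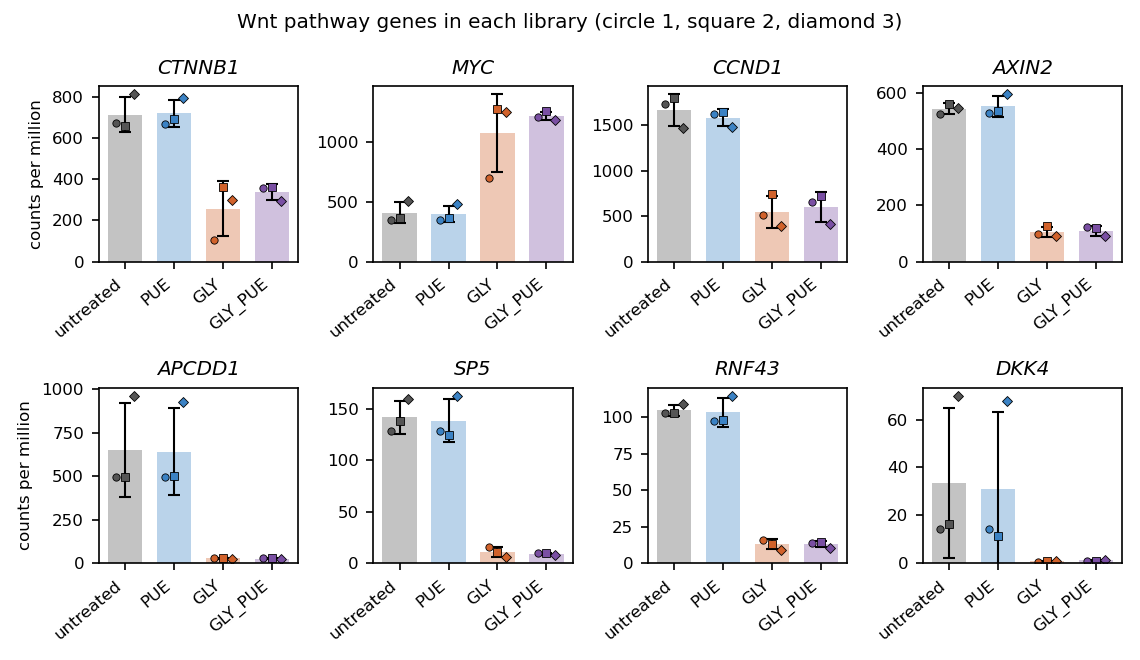
Levels of 8 Wnt pathway genes in CPM, scaled by library totals. Bars are means and error bars SD (n = 3), drawn down to 0 where the SD exceeds the mean, and symbols are single libraries. CTNNB1, CCND1, AXIN2, APCDD1, SP5, RNF43 and DKK4 were lower and MYC higher with GLY and GLY_PUE. Under TMM the calls of CTNNB1 and CCND1 were lost, with no change of sign.

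Genes of protein folding stress rose with GLY. HSPA5, an endoplasmic reticulum chaperone, went from 638 ± 8.16 to 4637 ± 2617 CPM (2.86, SE 0.37, adjusted p = 9.03e-05), and SDF2L1 (2.05), MANF (1.74) and HYOU1 (1.66) rose too. Of 12 genes of the unfolded protein response 11 rose (adjusted p = 1.61e-07, and adjusted p = 0.247 with an estimated correlation). Of 20 genes on the heat shock list, 6 were in the table. All 6 rose, with HSPA1A at 2.88, HSPA1B at 2.16, BAG3 at 1.44 and DNAJB1 at 1.07 (adjusted p = 2.5e-05, and adjusted p = 0.247 with an estimated correlation). Of 14 ATF4 targets 12 rose and 1 fell, with SESN2 (2.32), TRIB3 (1.91), CEBPB (1.46) and STC2 (1.40) higher (adjusted p = 1.61e-07, and adjusted p = 0.156 with an estimated correlation). Under TMM 12, 6 and 13 of these rose and none fell. Of 9 NRF2 targets 6 rose (9 under TMM), among them HMOX1 (2.67), SRXN1 (1.63), GCLC (1.16, a call lost without GLY replicate 3, 0.66) and TXNRD1 (1.12), with adjusted p = 0.000131 and adjusted p = 0.247 with an estimated correlation. Of 5 metallothionein and zinc genes 4 rose, MT2A (1.83), MT1X (1.73), MT1E (1.43) and MT1F (1.29), with adjusted p = 0.00125 and adjusted p = 0.247 with an estimated correlation.

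Targets of p53 and early response genes were higher as well. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 1.72 (SE 0.23), GADD45A by 2.26, SFN by 1.97 and PLK3 by 1.79. Of 11 p53 targets 8 rose and 3 fell (adjusted p = 9.52e-05, and adjusted p = 0.156 with an estimated correlation). Their highest member, at 2.32, is SESN2, which is also among the ATF4 targets, so these lists are not separate evidence. The immediate early and short-lived stress lists overlap as well. Of 18 immediate early genes 12 rose and 5 fell, with DUSP5 at 2.32, DUSP1 at 1.91 and KLF6 at 1.81 (adjusted p = 7.58e-05, and adjusted p = 0.247 with an estimated correlation). Of 8 short-lived stress transcripts 7 rose and 1 fell, with ATF3 at 1.96, IER2 at 1.01 and HEXIM1 at −1.60 (adjusted p = 0.000705, and adjusted p = 0.28 with an estimated correlation). Under TMM 8, 13 and 7 of these rose and none fell. Of 8 glucocorticoid targets, a list that shares members with the lists above, 5 rose and 2 fell (adjusted p = 0.00525, and adjusted p = 0.156 with an estimated correlation), with CEBPD at −1.17 but 0.02 under TMM, where 6 rose and 0 fell. Of 7 inflammatory genes 5 rose and 1 fell, with CSF2 at 2.54, CXCL8 at 2.57, NFKB2 at 1.11 and ICAM1 at −1.29 (adjusted p = 0.00625, and adjusted p = 0.247 with an estimated correlation). Under TMM 5 of them rose and 0 fell. CXCL8 lost its call without GLY replicate 3 (1.70; 3.22 without untreated replicate 3), and CSF2 was at 3.21 without untreated replicate 2. The libraries numbered 3 differed from the rest of their groups in these lists, with 3 of 9 NRF2 targets (median −0.14), 0 of 11 p53 targets (−0.24), 5 of 18 immediate early genes (−0.24, with 1 higher), 2 of 8 short-lived stress transcripts (−0.42) and 3 of 7 inflammatory genes (−0.53) called lower. These lists passed for number 3 (adjusted p = 0.00542, 0.021, 0.000574, 0.000574 and 0.00081), but adjusted p = 0.448, 0.406, 0.448, 0.406 and 0.0758 with an estimated correlation.

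Genes of cell division fell against untreated. PCNA, the sliding clamp of DNA replication, fell by 2.15 on the log2 scale (SE 0.28), E2F2 by 2.46, MCM4 by 1.37 and RRM2 by 1.37. All 21 tested genes of the G1 to S transition, of 30 on that list, fell (adjusted p = 0.00525, and adjusted p = 0.388 with an estimated correlation). The mitotic kinesin KIF20A was at −2.85 (SE 0.42), AURKA at −1.67, BIRC5 at −1.31 and CCNB1 at −1.29. All 24 tested genes of the G2 to M list, which holds 32, fell (adjusted p = 0.00525, and adjusted p = 0.513 with an estimated correlation). The medians of these lists, −1.37 and −1.43, lie near that of the other genes tested, −1.15, and under TMM 2 and 3 of them fell. In the libraries numbered 3 the G2 to M genes had a median of 0.42 against the rest of their groups, with 10 of 24 called higher (adjusted p = 0.00665, and adjusted p = 0.503 with an estimated correlation). For each list called with GLY, the value with an estimated correlation was the highest over the 16 alternatives.

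Of 3429 genes tested, 2890 passed in GLY against untreated, 674 higher and 2216 lower (76.7% lower), and 2856 (83.3%) had groups that do not overlap, where chance gives 10% for genes not selected for change, as these were by the authors. Outside the lists, and among called genes with an average log2 CPM of at least 1 and groups that do not overlap, KRT16 (5.50, SE 0.38), ROBO4 (4.81), CREB5 (4.78) and CRYAB (3.96) were among the largest increases, and EDN3 (−6.83, SE 1.37), TNFRSF11B (−6.60), NCALD (−5.30) and PLPPR4 (−5.10) among the largest decreases. Without untreated replicate 3, EDN3 was at −5.17 and PLPPR4 at −3.92, and without GLY replicate 3, CREB5 was at 4.08 and CRYAB at 3.32. Under TMM 1158 genes passed, 812 higher and 346 lower (29.9% lower). Whether most called genes were lower thus depends on the scaling. The shift of 1.13 by itself turns the sign of 515 of the 2890 genes (17.8%), those nearest 0 on the lower side, and 0 of these pass under TMM.

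In GLY_PUE against untreated, AXIN2 was at 110 ± 17.7 CPM (−2.31, SE 0.21, adjusted p = 2.07e-05), APCDD1 at −4.66, SP5 at −3.96, RNF43 at −3.03 and BMP4 at −2.77, and MYC rose by 1.58 (SE 0.26) and LGR5 fell by 4.90 on the log2 scale (−3.85 without untreated replicate 3, −6.42 without GLY_PUE replicate 3). Of 29 Wnt targets 25 fell and 3 rose (adjusted p = 0.000503, and adjusted p = 0.315 with an estimated correlation; 19 and 3 under TMM). CTNNB1 (−1.08, SE 0.35) and CCND1 (−1.48) fell, calls that TMM ends (−0.06 and −0.47), and APC did not pass (−0.45, SE 0.56, adjusted p = 0.443). HSPA5 rose by 2.88 with all 12 tested genes of the unfolded protein response (adjusted p = 2.89e-07, and adjusted p = 0.289 with an estimated correlation). Of the ATF4 targets 13 rose (adjusted p = 2.89e-07, and adjusted p = 0.179 with an estimated correlation), as did all 6 tested heat shock genes (adjusted p = 3.31e-05, and adjusted p = 0.289 with an estimated correlation). Of 11 p53 targets 8 rose and 2 fell (adjusted p = 0.000118, and adjusted p = 0.179 with an estimated correlation), and of 8 glucocorticoid targets 5 rose and 2 fell (adjusted p = 0.00508, and adjusted p = 0.179 with an estimated correlation). Of 9 NRF2 targets 7 rose (adjusted p = 6.76e-05, and adjusted p = 0.289 with an estimated correlation), and of 18 immediate early genes 12 rose and 2 fell (adjusted p = 3.98e-05, and adjusted p = 0.289 with an estimated correlation). Of 8 short-lived stress transcripts 7 rose and 1 fell (adjusted p = 0.000684, and adjusted p = 0.289 with an estimated correlation). Of 5 metallothionein and zinc genes 4 rose and 1 fell (adjusted p = 0.00508, and adjusted p = 0.289 with an estimated correlation), and of 7 inflammatory genes 3 rose and 1 fell (adjusted p = 0.0172, and adjusted p = 0.289 with an estimated correlation). Under TMM 8, 6, 9, 13, 7, 4 and 6 of these rose, in the order given, and none fell.

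The 21 and 24 cell division genes fell again (adjusted p = 0.00315 and 0.00508, and adjusted p = 0.339 and 0.554 with an estimated correlation), 3 and 2 of them under TMM. Of 4 YAP targets 3 rose, AXL (2.00), CYR61 (1.79) and F3 (1.15), with adjusted p = 0.0219 and adjusted p = 0.289 with an estimated correlation, while in the libraries numbered 3 the list had a median of −0.43, with 1 of 4 called lower (adjusted p = 0.021, and adjusted p = 0.448 with an estimated correlation). Outside the lists, and under the same limits on level and overlap, KRT16 (4.99), CREB5 (4.89), ROBO4 (4.61), PAK6 (3.81) and IL1R1 (3.56) were among the larger increases and EDN3 (−6.83), TNFRSF11B (−6.14) and NFE2 (−4.52) among the larger decreases. Without untreated replicate 3 EDN3 was at −5.16, and without GLY_PUE replicate 3 EDN3 was at −8.34, CREB5 at 4.19 and ROBO4 at 3.95. In all 2651 genes passed, 694 higher and 1957 lower (73.8% lower), and 2996 (87.4%) had groups that do not overlap. Chance gives 10% only for exchangeable libraries and genes not selected for change. Here the genes were selected and the libraries numbered 3 stand apart. Under TMM 1211 passed, 817 higher and 394 lower, and 308 of the 2651 had the other sign. The fold changes of GLY and GLY_PUE correlated at 0.963. Sharing the untreated libraries gave 0.502 in a simulation without shifts by replicate number, which does not describe these libraries. PUE and GLY share the untreated libraries too and correlated at 0.00873, where that simulation also gave 0.502. The genes were also selected for change, so 0.502 is no measure of chance for 0.963. With the replicate block 2926 genes passed, and the histone (adjusted p from 0.3 to 0.0354), interferon (0.0595 to 0.0481) and leukocyte lists (0.0818 to 0.0251) gained a call, where values over all alternatives ran up to 0.638, 0.339 and 0.289 with an estimated correlation. No other list call changed with this block.

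**Figure D3:**
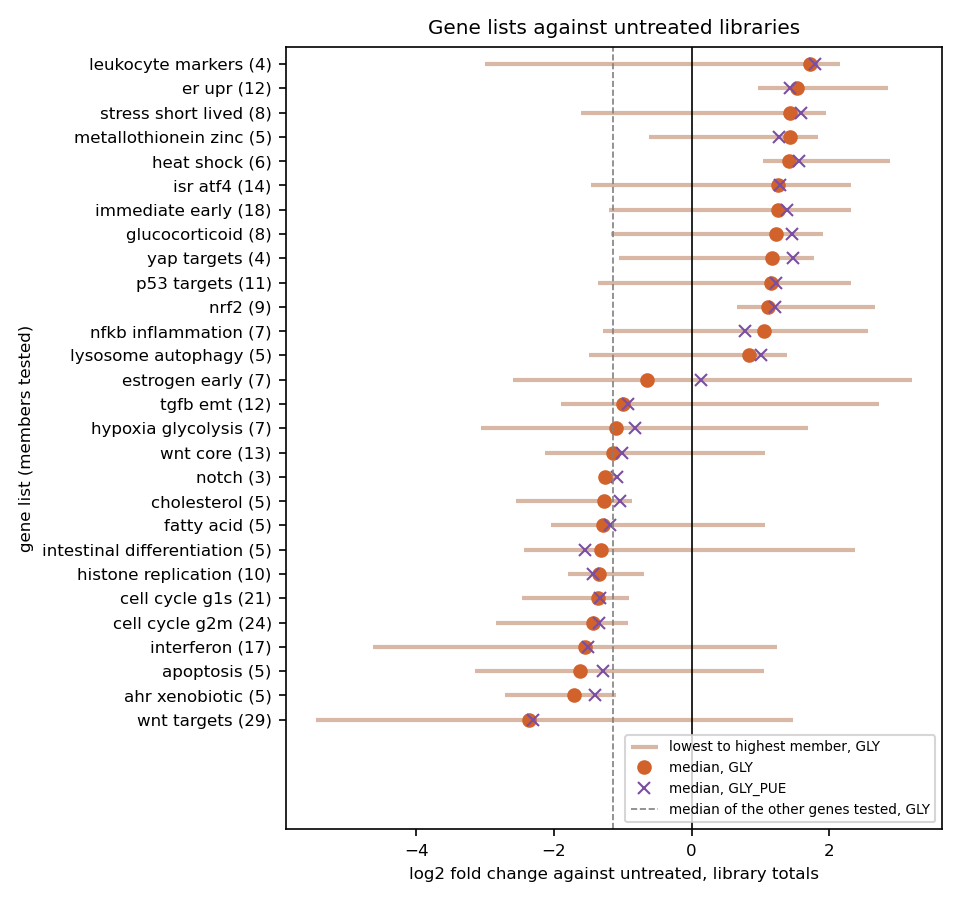
Median log2 fold change of each list against untreated with GLY (circles) and GLY_PUE (crosses), with the range of members for GLY, relative to library totals. The dashed line is the median of the other genes tested. TMM moves the values up, at the median by 1.13 (GLY) and 1.01 (GLY_PUE), which turns the sign of the medians of TGF-beta and early estrogen response genes for GLY and of TGF-beta, hypoxia and cholesterol genes for GLY_PUE.

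No change was shown in these genes with PUE alone, and the SEs of LGR5 and APC are too wide to place them near untreated levels. AXIN2 (0.02, SE 0.20), CTNNB1 (0.01, SE 0.34), MYC (−0.03, SE 0.26), CCND1 (−0.07, SE 0.27), LGR5 (0.12, SE 0.73) and APC (0.09, SE 0.56) did not pass. The smallest edgeR p-values, none past the threshold, were for TDRD10 (−1.54, SE 0.45), CORO7-PAM16 (3.03 CPM untreated and 0 in all 3 PUE libraries), ZNF660-ZNF197 (1.64 CPM and 0), ANKRD20A2 (−2.46, SE 0.87) and ARHGAP25 (1.16, SE 0.44). With edgeR 0 of 3429 genes passed, with 12 at an unadjusted p under 0.05. DESeq2 gave 0 and 4, limma-voom 0 and 14, and the replicate block 0 and 19. Far fewer genes fell under 0.05 than the share of 0.05 that chance gives, so these tests were conservative here. In the fit on these 6 libraries with the replicate block, 147 of 3260 genes had an unadjusted p under 0.05 and 1 passed, CORO7-PAM16. In the fit on both groups without number 3, 276 of 3236 genes had an unadjusted p under 0.05 and 6 passed. Both fits were added after the data had been examined. Groups did not overlap in 109 genes (3.18%), and 0 of 28 lists passed. Chance gives 10% for exchangeable libraries, which these are not, since those numbered 3 stand apart. Without the block, the 95% interval lay within a log2 fold change of 1 either way in 2090 of 3418 genes (61.1%). The simulation recovered 18% of changes of 2-fold, 56% of 3-fold and 80% of 4-fold. Both take their spread from the fit of all 12 libraries, in which those numbered 3 and GLY replicate 1 stand apart. They may therefore understate what untreated and PUE replicates 1 and 2 can show. By that fit, effects of PUE below 2-fold, and larger ones in part of the genes, cannot be excluded. The authors' columns mark 19 genes for this comparison, 10 of them read-through symbols against 20 of the other 3680 listed genes (Fisher's exact test, p = 2.03e-17). The test decides little, since all listed genes were called by the authors in some comparison. A gene not changed by GLY is listed only if called here or in GLY_PUE against GLY. The selection itself can therefore give such an excess.

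GLY_PUE against GLY gave no called gene. NNAT (1.60, SE 0.42), NOS1 (1.28, SE 0.33), TDRD10 (1.41, SE 0.42), SYNJ2BP-COX16 (−1.82, SE 0.54) and FAM72C (−3.34, SE 1.00) had the smallest edgeR p-values, none past the threshold (adjusted p = 0.959). CTNNB1 (0.40, SE 0.34), MYC (0.18, SE 0.26) and AXIN2 (0.06, SE 0.20) did not pass. Of 28 lists 0 passed, so no list, YAP and inflammatory genes included, was shown to differ between GLY_PUE and GLY. With edgeR 0 genes passed, with 57 at an unadjusted p under 0.05, and DESeq2 gave 0 and 49, limma-voom 0 and 59, the replicate block 0 and 115. Fewer genes fell under 0.05 here too than the share of 0.05 that chance gives, so these tests were conservative. Groups did not overlap in 167 genes (4.87%), where chance gives 10% for exchangeable libraries. These are not exchangeable, since those numbered 3 stand apart. The authors' columns mark 70 genes here, 43 higher and 27 lower, of which 12 are read-through symbols and 28 have groups that do not overlap. Without the block, the interval lay within a log2 fold change of 1 in 1362 of 3419 genes (39.8%), so by that fit effects of that size remain possible for most.

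The interaction, which asks whether PUE acts differently with GLY, gave 0 genes with edgeR (33 at an unadjusted p under 0.05), DESeq2 (22) and limma-voom (35). These counts, too, lie below the share of 0.05 that chance gives. TDRD10 (2.94, SE 0.62), CORO7-PAM16 (0 in all PUE and GLY libraries), ANKRD20A2 (3.72, SE 1.11), CNKSR2 (2.53, SE 0.77) and C17orf77 (2.01, SE 0.66) had the smallest edgeR p-values, none past the threshold (adjusted p = 0.999). AXIN2 was at 0.04 (SE 0.29) and CTNNB1 at 0.39 (SE 0.48). The interval lay within a log2 fold change of 1 in 617 of 3411 genes (18.1%).

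The comparisons against PUE share the GLY or GLY_PUE libraries with those against untreated and are not independent of them. KRT16 (6.09, SE 0.40), CREB5 (5.44), ROBO4 (4.52) and SPRR2D (4.07) were higher with GLY than with PUE, and EDN3 (−6.67), TNFRSF11B (−6.51), DKK4 (−5.35) and NCALD (−5.23) lower. In GLY_PUE against PUE, KRT16 (5.58, SE 0.39), CREB5 (5.54), ROBO4 (4.32) and PAK6 (4.30) were higher and EDN3 (−6.67), TNFRSF11B (−6.06), NXPH3 (−5.45) and PLPPR4 (−5.37) lower. PALM2-AKAP2, a read-through symbol, was higher in both (4.02, SE 1.61, and 4.35, SE 1.62), a call lost without PUE replicate 2 or 3 and, for GLY, without GLY replicate 2 or 3. Without PUE replicate 3, EDN3 was at −4.80 in both and DKK4 at −4.06, PLPPR4 at −4.68 and PAK6 at 5.76. Without replicate 3 of GLY or GLY_PUE, CREB5 was at 4.74 and 4.84, and without GLY_PUE replicate 3, ROBO4 was at 3.66 and EDN3 at −8.19. Of 29 Wnt targets 26 fell and 3 rose with GLY (adjusted p = 0.00133, and adjusted p = 0.356 with an estimated correlation), and 25 fell and 3 rose with GLY_PUE (adjusted p = 0.000703, and adjusted p = 0.331 with an estimated correlation). In all 2926 genes passed for GLY, 694 higher and 2232 lower, and 2669 for GLY_PUE, 705 higher and 1964 lower. Under TMM, which shifts these comparisons by 1.15 and 1.02, the counts were 1177 (821 higher, 356 lower) and 1232 (830 higher, 402 lower). Of 28 lists 13 passed for GLY and 15 for GLY_PUE, and 0 with an estimated correlation. With the replicate block the gene counts were 3097 and 2949, and the leukocyte list passed in both, interferon and YAP targets in GLY against PUE and histones in GLY_PUE against PUE. The estimated correlation was run only without the block, where these lists did not pass with the preset one either. There it gave leukocyte adjusted p = 0.261 and 0.289, interferon 0.356, YAP 0.356 and histones 0.63.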

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

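The libraries numbered 3 left out or given a term, and the fits on the compared groups with the block or without number 3, were chosen after the results were seen, as was the use of library totals in place of the planned TMM. Scaling changed the counts of all 4 comparisons of libraries with and without GLY: TMM gave 1158, 1211, 1232 and 1177 genes and RLE 1188, 1234, 1250 and 1204 for GLY and GLY_PUE against untreated, GLY_PUE against PUE and GLY against PUE. Signs turned for CEBPD (0.022 under TMM), TLE3 (0.018 under TMM) and TM7SF2 (0.39 under TMM, 0.30 under RLE) in GLY, and for IDI1 (0.065 under TMM, 0.031 under RLE) and TM7SF2 (0.011 under TMM) in GLY_PUE, all against untreated and none past the threshold there. With each library left out in turn the counts ran from 2407 to 2941 (GLY), 2133 to 2995 (GLY_PUE), 2187 to 3011 (GLY_PUE against PUE) and 2445 to 2964 (GLY against PUE), 0 throughout for PUE, and 0 to 1 for GLY_PUE against GLY and the interaction. That 1 gene was LIMS3 without GLY_PUE replicate 2 (−11.25 and −11.16), chosen after its values were seen. With 2 groups and no number 3 the counts were 1014 for GLY, 1215 for GLY against PUE, 2996 for GLY_PUE, 3028 for GLY_PUE against PUE and 6 for PUE, namely PLGLB2 (−8.12), CORO7-PAM16 (−8.81), GOLGA8R (7.05), GCLC (0.25), ANKRD20A2 (−2.33) and TXNRD1 (0.26), and with 2 groups and the block 1 for PUE, CORO7-PAM16 (−8.93); the cause was not tested. With an estimated correlation 0 lists passed in the 4 comparisons of GLY libraries with libraries without GLY, against 13, 14, 15 and 13 with the preset one. Fry, which asks another question, whether a list differs from no change and not from the other listed genes, gave 23 in each. With each library left out, 0 to 6 lists passed for PUE and 0 to 2 for the interaction, the 6 and 4 without PUE or untreated replicate 3, where a group then lacks its partner of that number. Without PUE replicate 3 the immediate early and short-lived stress lists turned direction in PUE and passed (adjusted p = 0.0044 and 0.000954, ranges 0.000723 to 0.998 and 0.000954 to 0.998), and NRF2 (0.000605), ATF4 (0.00627) and Wnt targets (0.00736) and histones (0.00993) passed too. Without untreated replicate 3 the immediate early (0.000723), short-lived stress (0.00111), cholesterol (0.0398) and inflammatory lists (0.0465) passed. The replicate block gave 3086 genes in GLY against untreated, where the numbers did not meet the criterion for pairing, and let YAP targets (adjusted p = 0.0226) and leukocyte markers (0.0189) pass, within ranges of 0.0226 to 0.349 and 0.0189 to 0.247. Of 9487 values of rule-named genes under alternatives, 9219 kept direction and side of the threshold, 230 lost a call (120 of them under TMM or RLE), 31 gained one and 7 turned direction. The share kept does not measure robustness. Most of these genes were picked by size or p-value in the same data. Many alternatives leave out a library of neither group, and a gene that stays uncalled counts as kept. Depth limits what a count of 0 can show to about 0.153 CPM.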

Other observations

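The gene lists and the counts of other splits below were set before the data were examined, while the tests on GLY replicate 1, on the libraries numbered 3 and on NRF2 targets were chosen after the results were seen. The lists below did not pass against the other listed genes with GLY. Most listed genes were lower (median −1.15), so a count of members that fell does not by itself set a list apart from them. Of 17 interferon genes 13 fell and 1 rose against untreated, with OAS2 at −3.35 (SE 0.25), OAS3 at −2.22 and IFIT3 at −1.55 (adjusted p = 0.0578; 5 fell and 1 rose under TMM), and CMPK2 went from 0.928 to 0.0314 CPM. The interferon list passed in GLY_PUE against PUE (14 of 17 fell, adjusted p = 0.0488, and adjusted p = 0.349 with an estimated correlation). All 5 tested aryl hydrocarbon receptor targets, of 20 on that list, fell, UGT1A6 (−2.43), CYP1B1 (−2.71), CYP1A1 (−1.71) and AHRR (−1.42) among them (adjusted p = 0.115, with 2 under TMM). Of 12 genes of TGF-beta signalling 4 rose and 7 fell (adjusted p = 0.264; 4 and 0 under TMM), with MMP14 at 1.46 (SE 0.20) and LTBP2 at −1.90, and the median turned from −0.998 to 0.13 under TMM. Of 7 hypoxia genes 3 rose and 4 fell (adjusted p = 0.502; 3 and 2 under TMM), with NDRG1 at 1.46, SLC2A3 at −1.46, ANKRD37 at −3.07 and EGLN3 at −2.73, the last 2 at −2.17 and −2.08 without untreated replicate 3. Of 5 cholesterol genes 5 fell (adjusted p = 0.452; 0 under TMM), with IDI1 at −1.25 and TM7SF2 at −0.86, the last at 0.39 under TMM. IDI1 lost its call without untreated replicate 3 (−0.80), and TM7SF2 without untreated replicate 3, GLY replicate 2 or GLY replicate 3 (−0.66, −0.74 and −0.66).

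Of 5 intestinal differentiation genes 4 fell, such as CDX2 (−2.44), and CEACAM1 rose (2.38) (adjusted p = 0.548; 1 fell and 1 rose under TMM). Of 5 fatty acid genes 4 fell, such as ACACB (−1.87), and ELOVL1 rose (1.06) (adjusted p = 0.612; 1 and 1 under TMM), and of 5 apoptosis genes 4 fell, such as BMF (−3.15) and BCL2 (−1.62), and TNFRSF10B rose (1.06) (adjusted p = 0.486, with 1 and 1 under TMM). Of 7 early estrogen response genes 3 rose, such as AREG (3.21), and 3 fell, such as MYB (−2.59) (adjusted p = 0.259, with 3 and 1 under TMM). Of 5 lysosome and autophagy genes 3 rose, such as MAP1LC3B (1.39), and 1 fell (adjusted p = 0.115, with 3 and 0 under TMM). All 3 tested Notch genes, of 18 on that list, fell, such as NOTCH1 (−1.12) (adjusted p = 0.452, with 0 under TMM). Of 10 replication histones 7 fell, such as HIST2H2BE (−1.80) (adjusted p = 0.452, with 0 under TMM), and of 4 YAP targets 3 rose, such as AXL (1.79) (adjusted p = 0.0578, with 3 under TMM). Of 4 leukocyte markers 3 rose, such as CD68 (2.16), and 1 fell (adjusted p = 0.0585, with 3 and 1 under TMM). TMM moves these values up by 1.13 at the median.

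GLY replicate 1 differed from GLY replicates 2 and 3 in a way that followed GC content. Across 1914 genes its deviation correlated with the GC content of the transcript at a rank correlation of 0.814, and median deviations ran from −1.62 in the fifth of genes lowest in GC to 0.61 in the highest, while GLY_PUE against untreated gave −0.02. The slope of its effect on that of the other GLY libraries was 1.02 (SE 0.0175). This slope cannot decide on a shorter treatment. Both effects share the untreated mean, the SE takes genes as independent, and the deviation with GC content enters the same slope. A lower depth is argued against by the library total of GLY replicate 1, 99.2% of that of the other GLY libraries. A bias in this library by GC content stays open as a candidate explanation, with transcript length also related to the deviation (−0.46). Given length, the rank correlation with GC content was 0.79, and given GC content that with length was −0.35. A smooth curve on GC content took up 64.1% of the variance of the deviation.

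The libraries numbered 3 differed from numbers 1 and 2 by a term common to all groups in 804 genes, 622 higher and 182 lower, not each of which deviated in every group. Replication histones had a median of −1.08 in them, with 8 of 10 lower (adjusted p = 3.48e-10, and adjusted p = 0.0211 with an estimated correlation). The deviation of replicate 3 correlated between groups at 0.275 or more, as a batch shared by these libraries may give. Bias by GC content or length common to them is argued against by rank correlations that came no farther from 0 than −0.19 and −0.142 in the untreated, PUE and GLY_PUE libraries, while GLY, whose replicate 1 follows GC content, gave −0.73 and 0.28. The labels give no batch, and no biological explanation was tested.

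NRF2 targets looked higher with PUE in replicates 1 and 2, a pattern noticed after several subsets of libraries had been looked at and so only a hypothesis. Median log2 ratios of the 8 members with enough counts were 0.20 and 0.20 in pairs 1 and 2, and TXNRD1 and GCLC passed there without number 3 (0.26 and 0.25). In pair 3 the median was −0.0313, and with PUE on top of GLY it was 0.12 and −0.244 in pairs 2 and 3. Pair 1 there (0.78) uses GLY replicate 1, and random lists of its size spread with an SD of 0.472, so it says nothing of NRF2. An effect of PUE of equal size in every pair, with or without GLY, and its absence cannot be told apart, since each pair holds 1 library per group and gives no spread between libraries.

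Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. As many genes as the real split were called by 1 of 10 splits for GLY against untreated (real 2890, highest other 1), GLY_PUE against untreated (2651, 0), GLY_PUE against PUE (2669, 0) and GLY against PUE (2926, 0), and by 10 of 10 for PUE against untreated (0, 0) and GLY_PUE against GLY (0, 2). The listed genes were selected by the authors' calls on the real groups, 2878 of them in GLY against untreated. High counts for the real splits were thus favoured in advance and are no independent support. For the interaction all 100 of 100 regroupings of the 12 libraries called at least the real 0 genes, which a real count of 0 fixes in advance, here and for the 10 of 10 above, and decides nothing. The highest other called 1135, which points to the structure of the samples, since regroupings mix libraries with and without GLY.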
